A study of Drosophila melanogaster with 2 samples.

How the data were processed

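The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Sry-delta, a zinc finger protein of Drosophila melanogaster encoded by serendipity delta. The 2 libraries came from whole embryos of both sexes, collected 0 to 24 hours after egg laying. The flies carried a transgene for Sry-delta with green fluorescent protein (GFP) at its C-terminus, and chromatin was sheared by sonication and precipitated with an antibody against GFP, per the labels. The libraries are labelled as biological replicates 3 and 4 of 1 group. No input or mock library was analysed here, and no group contrast was possible.

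Peak lists in the narrowPeak layout were used for each library, for both libraries pooled, and for an optimal set. Per the README files deposited with the samples, each replicate list was called from that library's alignment against a control, the pooled list from both alignments against a control, and the optimal set from these lists by the irreproducible discovery rate (IDR). The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. Each replicate list and the pooled list held 30000 peaks, and the optimal set held 6318 peaks in genome build dm6 and 6113 in dm3. The deposited signal value of a peak is the authors' own measure of its height, has 1 scale per list, and was used only to rank and describe peaks. The deposited −log10 q value was at its maximum for all 6318 optimal dm6 peaks, so it carried no rank among them and was used only as an alternative. Read totals were not analysed here, so the depth of each library is unknown. Confidence intervals for shares are exact Clopper-Pearson intervals at 95% and cover counting error over peaks or genes only. Where no member of a list was bound, the limit printed is 3 counts of its members, which lies slightly below the upper end of the two-sided exact interval.

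The coordinates of the dm6 lists were used with the Release 6 genome sequence and with the Ensembl release 115 annotation (FlyBase 6.54), on the 6 arms 2L, 2R, 3L, 3R, 4 and X. Coordinates are 1-based. A summit was the start of a peak plus its deposited offset. Of the optimal peaks, 837 shared their region with a summit of higher signal, so the 6318 summits lay in 5481 regions. Of 835 such secondary summits that could be paired with the highest one of their region, 93.7% lay to its right in genome coordinates, at a median offset of 203 bp. The results other than rank agreement and X density were therefore also computed with 1 summit per region, an alternative added after the data had been seen.

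Replicate lists were compared by the percent of the 6318 highest-signal peaks of replicate 3 that overlapped a peak of the same number from replicate 4 by at least 1 bp, against 1000 shuffles within chromosomes in a one-sided permutation test. Signal in both replicates at the optimal peaks was compared by Spearman's rho across peaks. Summits within 500 bp of a protein-coding transcription start site were counted against 1000 shuffles of the peaks. Genes with a summit within 500 bp of any of their start sites were counted in 33 gene lists, by two-sided Fisher exact tests against the remaining protein-coding genes (13945 in all) or, for non-coding lists, the remaining annotated genes (18164 in all), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. A list of microRNA precursors had no member in the annotation and was not tested. Gene symbols that had changed were brought up to date for 19 entries, and 6 entries of the lists matched no gene of their own.

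Sequence matches on either strand were sought within 100 bp of the summit and in 201 bp windows centred 500 bp to each side. Shares at the summits were compared with the mean of the flanks, and an exact McNemar test used the right-hand flank. The Sry-delta in vitro consensus was YTAGAGATGGRAA with at most 2 mismatches, and 11 other motifs formed a panel with Benjamini-Hochberg adjustment. All 7-mers were counted within 50 bp of the summit and in 101 bp windows centred 300 bp to each side, with the same test and adjustment, and the 10 with the highest ratio among those in at least 2% of peaks were named. Density on the X was compared with the autosome arms by a two-sided exact binomial test. The 1579 optimal peaks with the highest signal and the 1579 with the lowest were compared by two-sided Fisher exact tests.

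The comparisons, lists, motifs, named-gene rule and most alternatives were fixed before the data were examined. Named genes were those nearest to the 15 optimal peaks with the highest signal, all members of the lists for the serendipity gene cluster and the maternal anterior system, up to 4 bound members of each other list past its test, and up to 2 of each list not past it. A gene taken by this rule is not reported here. Alternatives covered the window around start sites, the choice of start sites, the overlap, the number of peaks, the flanks, the mismatches, the k-mer length, each replicate alone, and the dm3 lists. No dm3 genome was used here, so the largest peak end on each arm stood in for its length in the dm3 shuffles and density. On simulated data, the code recovered a planted 7-mer, 100% of planted consensus windows and a planted gene list, called 1 of 200 random lists, and called 2 unrelated 7-mers of 8192. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Peaks and genes are not independent replicates, so the p-values describe these peak lists and not the spread between embryo collections. Signal tracks and alignments were not used here.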

Results

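Binding of GFP-tagged Sry-delta was mapped by ChIP-seq in whole embryos aged 0 to 24 hours. Sry-delta is a zinc finger transcription factor with a ZAD domain, a dimerisation domain common among insect zinc finger proteins. The data form 1 group of 2 biological replicates, labelled 3 and 4, and the comparisons are between the replicates, between peaks and the rest of the genome, and among peaks of different signal. The optimal set of 6318 peaks in build dm6 was used throughout. Signal values are the authors', and the sequencing depth is unknown.

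The strongest peaks lay at the same promoters in both embryo collections. RpL32, which encodes a protein of the large ribosomal subunit, had the highest signal in the optimal set (7028) and ranked 1 in each replicate. The Sry-delta gene itself ranked 43, with signals of 1594 in replicate 3 and 2144 in replicate 4. Both peaks lie within 10 kb of the Sry-delta gene, where extra copies from the tagging construct may raise signals. Of the 6318 highest-signal peaks of replicate 3, 89.6% overlapped those of replicate 4, against a mean of 4.32% and a maximum of 5.35% for shuffled peaks (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give). In the other direction the overlap was 83.7%. Across the 6296 optimal peaks found in both replicate lists, Spearman's rho between the replicates' signals was 0.907 and Pearson's r of the log2 signals was 0.93. These are correlations across peaks, which are not independent replicates, and the optimal set was itself chosen from these lists for reproducible ranks, so they are no independent measure of it. The log2 ratio of replicate 4 over replicate 3 had a median of 0.48 and an SD of 0.53. Against all 30000 peaks of replicate 4, overlap fell with rank. It went from 100% for ranks 1 to 1000 of replicate 3 to 90.9% for ranks 8001 to 9000 and 42.2% for ranks 29001 to 30000. For whole lists the shuffled mean was 19.8%. The −log10 q values gave a rho of −0.00797, because 5963 of the optimal peaks in replicate 3 and 6304 in replicate 4 shared the top value.

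**Figure D1:**
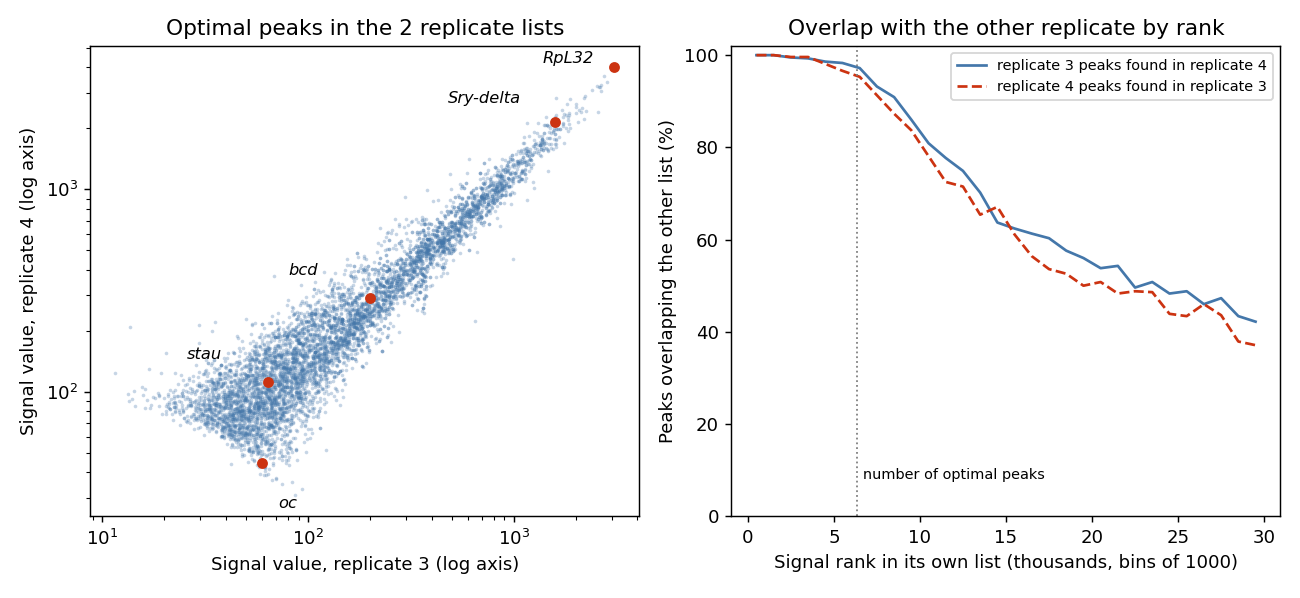
Left, signal of each optimal peak in replicate 3 against replicate 4, on log axes, with named genes in red; right, percent of peaks in each bin of 1000 ranks that overlapped any peak of the other replicate's list. The points follow a line with rho of 0.907, and overlap falls from 100% to 42.2% for replicate 3.

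Sry-delta was found mainly just upstream of protein-coding genes. The 15 highest peaks all lay within 500 bp of a start site, among them those of RpS29 (small ribosomal subunit; 3R, 9777626 to 9778474, signal 5899), Rpn6 (proteasome lid; 2R, 14751882 to 14752943, signal 6155), CycB (mitotic cyclin; 2R, 22806567 to 22807449, signal 5744), Daxx (a histone chaperone; 2L, 6480286 to 6481731, signal 5454) and Ubc6 (a ubiquitin-conjugating enzyme; 3R, 4952197 to 4953086, signal 4977). Besides RpL32, the others in order of signal were Mapmodulin, FAM21, CG8176, CG2924, Shc, RhoGAP93B, Pep, Jasper and CG15118, with signals from 6331 down to 4625. Peaks are named by the nearest coding start, and several were shared. Those of RpL32, Rpn6 and FAM21 also lay within 500 bp of starts of CG7943, ave and CG11180. The CG8176 peak did so for Kdm3 and mRpL47, and those of Daxx, Shc and CG15118 for Sec61alpha, Atat and CG15111. In total, 4783 summits (75.7%, exact 95% interval 74.6% to 76.8%) lay within 500 bp of a coding start site, against a mean of 11.4% and a maximum of 12.6% for shuffled peaks (one-sided permutation p = 0.001, the smallest the shuffles can give). Their median distance was 55 bp, and 79.5% of them were upstream of the nearest start. Sequence outside protein-coding genes, which includes non-coding genes, held 54.1% of summits and 32.8% of the genome. Within protein-coding genes, 5' untranslated regions held 16.9% against 3.38%, introns held 25.4% against 42.1%, and coding exons held 2.15% against 16.7%. The share near start sites was 95.8% among the 1579 peaks with the highest signal and 56.2% among the 1579 with the lowest (odds ratio 17.8, two-sided Fisher exact p = 6.3e-168). Pooled peaks that overlapped no optimal peak had a share of 20.5%.

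The cluster that contains the Sry-delta gene was bound at several of its own promoters. On 3R, a peak from 30043020 to 30043745 had its summit 8 bp from the start of Sry-delta (signal 3721). A peak from 30039324 to 30040035 (signal 2144, rank 243) lay between janA and the start shared by Sry-alpha, which acts in cellularisation, and the paralog Sry-beta. The RpL32 peak (30045731 to 30047037) lay on the other side of Sry-delta. No optimal summit was within 500 bp of janB or ocn, which are expressed in the testis. Bound members numbered 4 of 6, which did not pass the test against 39.0% of other coding genes (odds ratio 3.12, exact adjusted p = 0.256). With a window of 1000 bp, in which 6 of 6 were bound, it passed (exact adjusted p = 0.00905). These genes are neighbours that share peaks, so the test counts single peaks repeatedly and its genes are not independent. The peak at rank 243 counts for janA, Sry-alpha and Sry-beta, and within 1000 bp also for janB (978 bp from its summit).

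**Figure D2:**
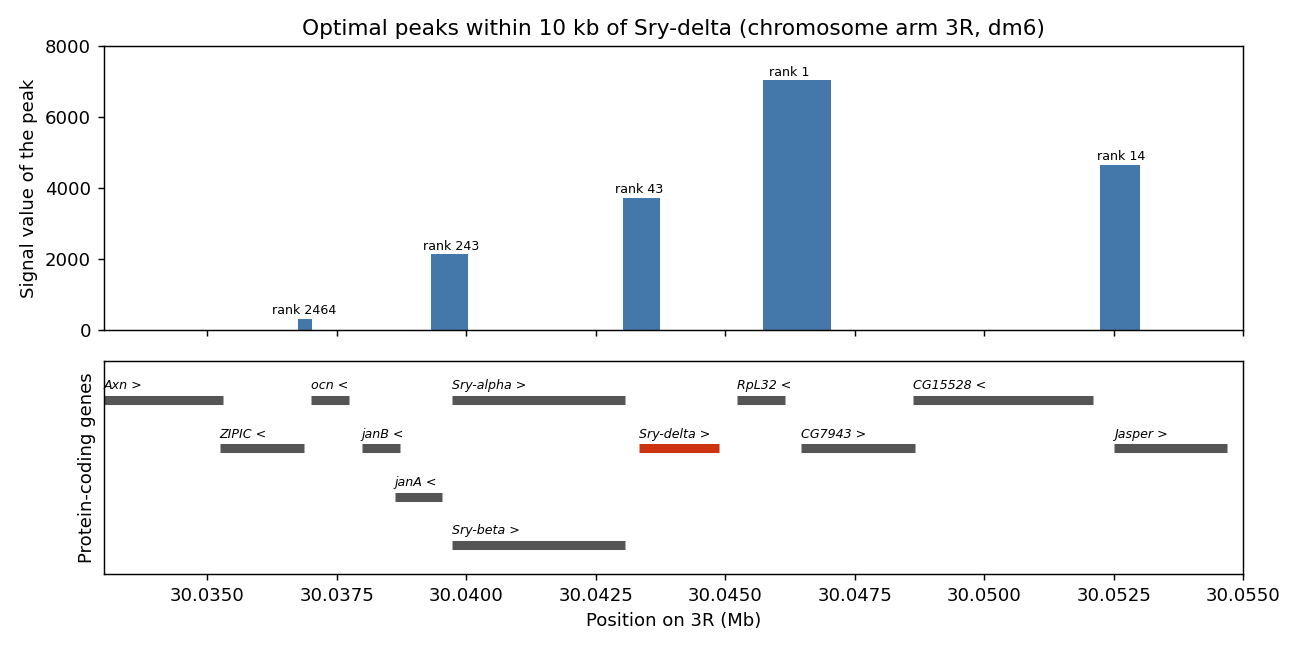
Optimal peaks within 10 kb of the Sry-delta gene on arm 3R of dm6, with bar height showing the signal and labels showing the rank, above the protein-coding genes of the region with their direction. The RpL32 peak has a signal of 7028, the Sry-delta peak 3721 and the peak shared by janA, Sry-alpha and Sry-beta 2144.

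The maternal anterior system list is not limited to genes of the anterior, and shares nanos with the maternal posterior list. Its member bcd, the anterior morphogen gene, had a peak 158 bp from its start (3R, 6759373 to 6759845). That peak had a signal of 480 and rank 1698. Higher signals were found at Vps36, a sorting protein gene needed for bcd RNA localisation (3852, rank 37), nanos, a translational repressor gene (1950, rank 296), and exu, which acts in bcd RNA localisation (1640, rank 421). The peak at stau, an RNA-binding protein gene, was weaker (173, rank 4104), and osk, pum and swa had no optimal summit within 500 bp. The list had 5 of 8 members bound and did not pass the test (odds ratio 2.60, exact adjusted p = 0.314). Without replicate 4 the odds ratio was 4.79 (exact adjusted p = 0.0753).

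Genes for basic cellular machinery were bound far more often than other genes. All 24 genes of the housekeeping list had a summit within 500 bp, among them His2Av, a histone variant gene (signal 3071), and Hsp83, a chaperone gene (1857), against 38.9% of other coding genes (exact adjusted p = 4.59e-10). With 0.5 added to each cell the odds ratio of this list was 76.8. The plain odds ratio, with nothing added, was 36.7 without replicate 3, 17.6 without replicate 4 and 11.1 with 1 summit per region. These plain values are not on the same footing as 76.8. Ribosomal protein genes were bound in 79 of 87 cases (odds ratio 15.6, exact adjusted p = 3.93e-23), with RpL7 (signal 3484) bound as well as RpL32 and RpS29. Mitochondrial ribosomal proteins followed with 63 of 73 bound (odds ratio 9.94), led by mRpL47 (5760), whose peak also serves CG8176. Proteasome genes were bound in 27 of 32 cases (odds ratio 8.47), with Prosalpha7 at 1784 and Rpt6 at 1717. Mediator and TFIID subunits, which act in transcription initiation, were bound in 32 of 39 cases (odds ratio 7.17, and 10.9 without replicate 4), led by Taf7 (4418) and MED27 (3697). Translation initiation factors were bound in 31 of 44 cases (odds ratio 3.74), with eIF3c at 4143 and eIF4G2 at 2164. Cell cycle genes were bound in 26 of 33 cases (odds ratio 5.82), with CycB at 5744, CycA at 2922, the replication helicase gene Mcm5 at 2370 and the mitotic kinase gene aurA at 2252. The exact adjusted p-values of these last 5 lists ran from 3.58e-16 for mitochondrial ribosomal proteins to 5.98e-05 for translation initiation factors. With the stricter set of peaks the odds ratio fell to 5.57 for housekeeping genes, 8.86 for ribosomal proteins, 3.58 for mitochondrial ribosomal proteins, 3.61 for Mediator and TFIID and 3.78 for cell cycle genes, and these lists still passed.

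Genes listed for chromatin architecture and for Sry-delta's own protein family were also bound more often. Insulator and architectural protein genes had 22 of 25 members bound (odds ratio 11.5, exact adjusted p = 1.26e-06), among them Pep (4656), the cohesin genes SMC1 (3203) and SA1 (1942), and pita (2194), which encodes an insulator-binding protein. Its odds ratio was 6.38 without replicate 3, 6.40 without replicate 4 and 3.54 with the stricter peaks, and it passed in each. The ZAD zinc finger list had 19 of 27 members bound (odds ratio 3.72, exact adjusted p = 0.00211), with CG9215 (2758) after Sry-delta and before pita and Sry-beta. Its 27 genes were a chosen list, and the share over the whole family was not measured.

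Tissue-restricted gene families were bound less often, and so were replication-dependent histone genes and pair-rule genes. No odorant receptor gene of 59 was bound (exact adjusted p = 9.26e-13), and a count of 0 allows a share of up to 5.08% (3 of 59). Gustatory receptor genes had 1 of 60 bound (Gr63a, signal 160), ionotropic receptor genes 2 of 60 (Ir60e, 799, and Ir31a, 457), cuticle protein genes 1 of 91 (Lcp9, 149) and cytochrome P450 genes 2 of 77 (Cyp6u1, 1616, and Cyp310a1, 223). The exact adjusted p-values of these lists ran from 9.21e-18 for cuticle proteins to 5.2e-10 for ionotropic receptors, whose odds ratio was 0.0535 and, without replicate 4, 0.113. Gut serine proteases had 0 of 24 bound (exact adjusted p = 1.58e-05), which allows a share of up to 12.5% (3 of 24). Replication-dependent histone genes had 0 of 111 bound (exact adjusted p = 1.53e-23), but they lie in a repeated cluster where unique reads are hard to place. Pair-rule segmentation genes had 0 of 10 bound (exact adjusted p = 0.0139), which allows a share of up to 30% (3 of 10), and this list did not pass with the stricter set of peaks (exact adjusted p = 0.104).

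Other developmental lists did not pass the test. Gap genes had 1 of 11 bound (oc, a head patterning gene, signal 104). In replicate 4 the oc peak had a signal of 44.3 and rank 8291. With replicate 4 alone, only as many top peaks as the optimal set holds were used, so oc was not counted as bound. Hox cluster genes had 1 of 12 bound (bcd), and early zygotic genes 1 of 11 (Sry-alpha, by the peak it shares with janA and Sry-beta). Segment polarity genes had 2 of 14 bound (smo, the Hedgehog signal transducer gene, 2641, and arm, the beta-catenin gene, 591). Neurogenesis genes had 5 of 26 bound (brat, 1614, and neur, 504), mesoderm and muscle genes 4 of 20 (Mef2, 1209, and tin, 319), and gut and fat body genes 4 of 14 (fkh, 385, and lin, 337). Maternal posterior genes had 9 of 17 bound (nanos, 1950, and mago, 1725), dorsoventral and terminal genes 6 of 19 (pll, 781, and tor, 766), and zygotic genome activators 2 of 4 (Trl, 217, and Clamp, 204). Exact adjusted p-values of these 10 lists ran from 0.0559 for Hox genes to 0.646 for zygotic genome activators. With a window of 1000 bp the gap, Hox, early zygotic and neurogenesis lists passed as lower (exact adjusted p from 0.0275 to 0.0409), as did the dorsoventral and mesoderm lists with 250 bp (0.0432 and 0.0296) and the gap list with replicate 4 alone (0.0143).

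Non-coding genes were bound less often than other annotated genes. tRNA genes had 12 of 290 bound (4.14% against 32.3%, odds ratio 0.0906, exact adjusted p = 3.55e-31). snoRNA genes had 20 of 269 bound (odds ratio 0.169) and the long non-coding RNA list 282 of 3261 (odds ratio 0.162). The last list was taken by annotation class and includes very short entries, such as that at 25646560 to 25646581 on 3R. With a window of 1000 bp the odds ratios of tRNA and snoRNA genes were 0.206 and 0.588, and both lists passed. Several of the highest of these peaks lay at coding promoters, such as that of lncRNA:CR45463 at Daxx (5454) and that of snoRNA:Psi18S-1275 at RpS29 (5899). For snRNA genes, 6 of 32 were bound (odds ratio 0.494, exact adjusted p = 0.159), a list that passed as lower with the stricter set of peaks (exact adjusted p = 0.00159), with snRNA:U1:95Ca at 199 and snRNA:U6:96Ab at 186. The highest tRNA peaks were near tRNA:Trp-CCA-2-2 (2217) and tRNA:Gly-GCC-1-13 (1680).

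**Figure D3:**
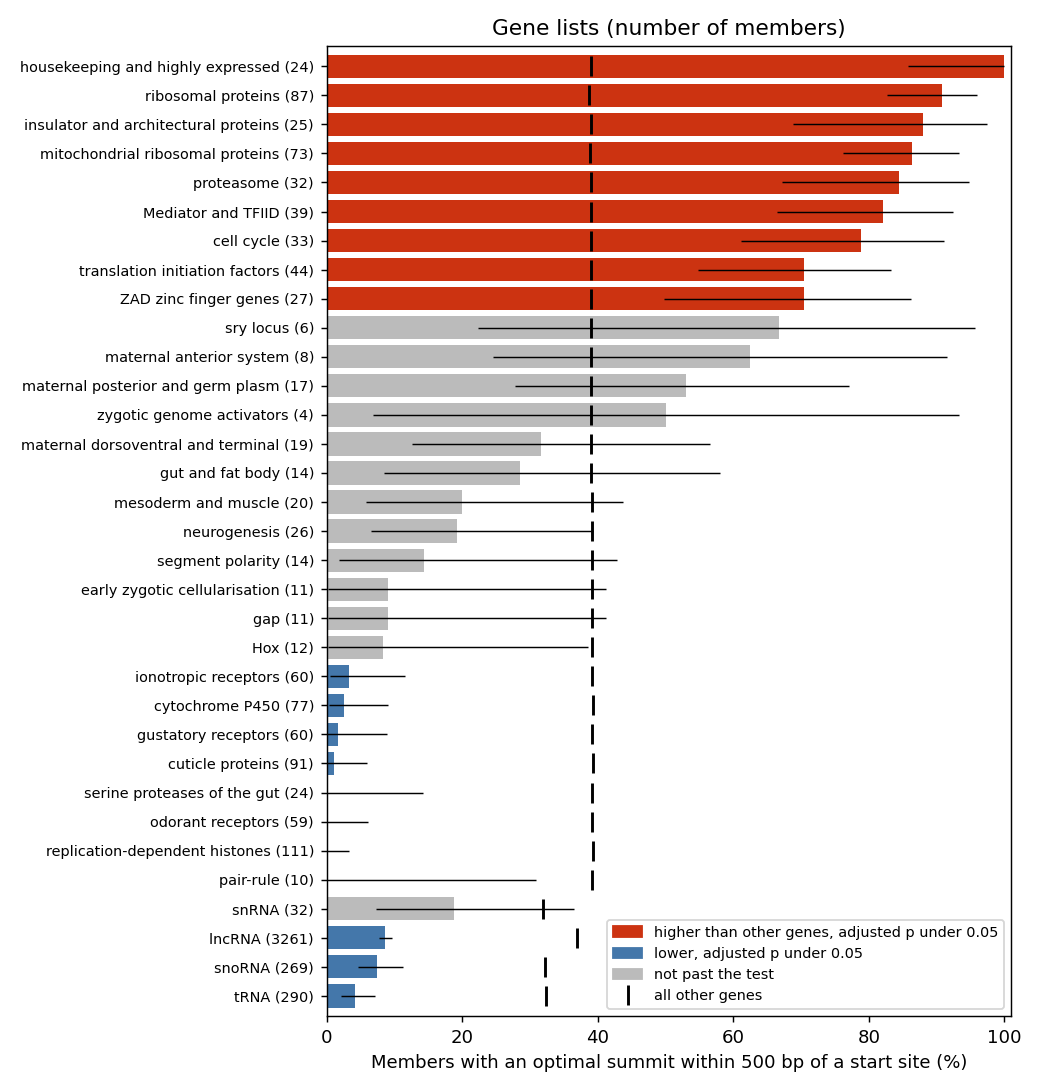
Percent of members of each gene list with an optimal summit within 500 bp of a start site, with exact 95% intervals as lines and the percent of all other genes as black ticks. Red bars are higher and blue bars lower at an adjusted p under 0.05, and grey bars did not pass; the ribosomal protein list stands at 90.8% and the cuticle protein list at 1.10%.

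The sequence that Sry-delta binds in vitro was found under a minority of summits. A match with at most 2 mismatches lay within 100 bp of 423 summits (6.70%, exact 95% interval 6.09% to 7.34%) against 1.61% of flanking windows, a ratio of 4.17 (exact McNemar p = 5.37e-50). With at most 1 mismatch the shares were 1.33% and 0.135%, a ratio of 9.88, and with at most 3 they were 26.4% and 15.1%, a ratio of 1.74. The match rose with signal, from 2.66% of the 1579 lowest peaks to 17.4% of the 1579 highest (odds ratio 7.72, two-sided Fisher exact p = 2.93e-47). The peaks of SMC1, eIF3c and 14-3-3zeta held a match with 1 mismatch, and that of mago, a germ plasm and exon junction gene, an exact match. The site of the paralog Sry-beta was found at 1.46% of summits against 0.902% of flanks (ratio 1.61, exact adjusted p = 0.000345).

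The DNA replication-related element (DRE, TATCGATA), bound by the transcription factor DREF and the insulator protein BEAF-32, had the highest ratio of the panel. It lay under 948 of the 6318 summits (exact 95% interval 14.1% to 15.9%) against 0.712% of flanks, a ratio of 21.1 (exact adjusted p = 2.53e-224), and the ratio was 40.1 within 50 bp of the summit. Motif 1, a core promoter element bound by M1BP, followed with 13.9% against 1.16% (ratio 12.0), CTCF with 2.20% against 0.562% (ratio 3.92), Motif 7 with 24.4% against 6.69% (ratio 3.64) and Motif 6 with 10.9% against 4.24% (ratio 2.58). The TATA box (ratio 1.37) and the E-box (ratio 1.36) were also higher. The site of Zelda, an activator of the early zygotic genome, was lower, at 0.807% against 1.41% (exact adjusted p = 0.000407). GAGA repeats were lower by a ratio of 0.777 (exact adjusted p = 0.0144), which did not hold when replicate 3 was used alone (ratio 1.02) or with flanks 1000 bp away (0.913). The Initiator did not pass (ratio 1.02, exact adjusted p = 0.186). The motifs differ in length and in mismatches allowed, so these ratios do not rank the sites.

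An unbiased count of 7-mers returned the same core. Of 8192 7-mers, 781 were higher under the summits and 1162 lower at an adjusted exact p under 0.05, and 9 of the 10 with the highest ratio contained CGATA. CTATCGA led, in 14.8% of peaks against 1.62% of flanks (ratio 9.12), and ATCGATA was in 21.6% against 2.49% (ratio 8.67). The exception was AGCCCTG, in 3.24% against 0.562% (ratio 5.77). With 1 summit per region, with flanks 500 bp away or with the stricter peaks, all 10 of the highest contained CGATA. The ratio of CTATCGA was 15.2 with 1 summit per region and 19.1 with flanks 500 bp away. The setting with 1 summit per region differs from the main one only in leaving out the secondary summits, so its change comes from them. How far they account for the change with flanks 500 bp away was not tested.

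**Figure D4:**
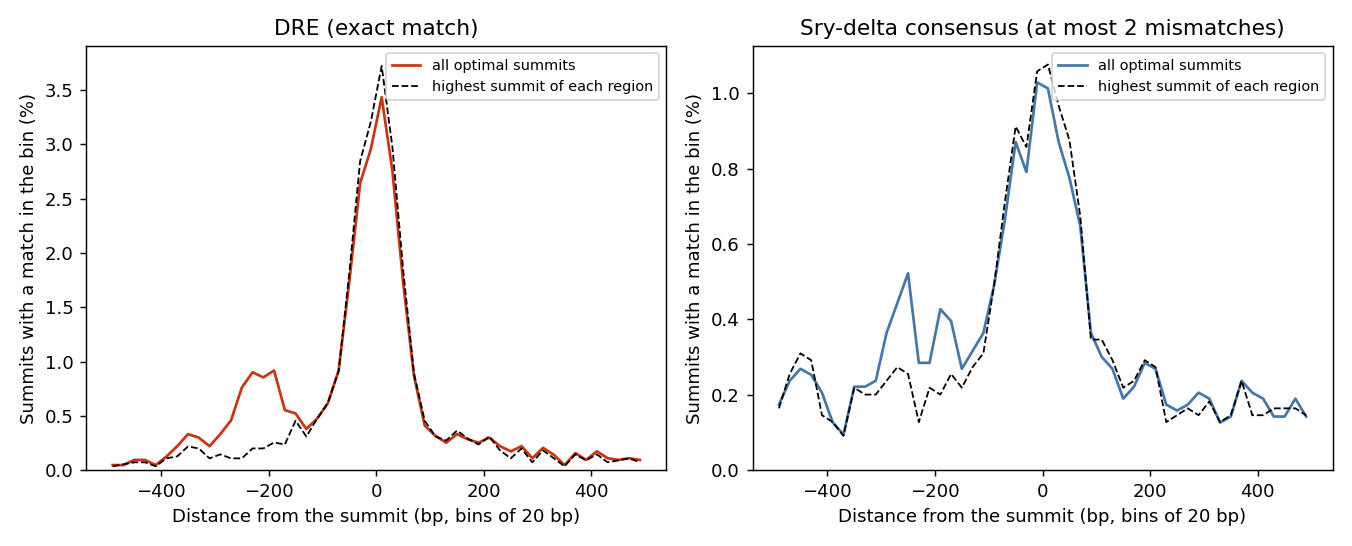
Percent of summits with a match in bins of 20 bp around the summit for the DRE, left, and the Sry-delta consensus, right, over all optimal summits (solid) and over the highest summit of each region (dashed). Both sites peak at the summit, at 3.43% and 1.03% per bin for all summits, and the rise near 240 bp to the left is seen with secondary summits included.

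Peaks were denser on the X than on the large autosome arms 2L, 2R, 3L and 3R. The X carried 53.8 optimal peaks per Mb and these arms from 43.2 (3L) to 48.1 (2R), a ratio of 1.18 for the X over the 4 arms (two-sided exact binomial p = 3.4e-07, 1267 and 4982 peaks). Per coding start site the ratio was 1.23, and in the dm3 lists it was 1.10, with the largest peak end on each arm standing in for the arm length. The small arm 4, left out of these ratios, carried 51.2 peaks per Mb, and 48.6 peaks per 100 coding start sites against 38.7 on the X.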

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

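The tests on Motif 1, Motif 6 and Motif 7, on the window around Sry-delta and on matches between builds were chosen only after the results had been seen. Those on promoter location, tRNA genes, base composition and likeness to the DRE were written down before their results. The design has 1 group and no control library was analysed here, so no biological explanation was tested.

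In the dm3 lists, 14 optimal peaks lay on heterochromatic or unplaced sequence that the main comparisons did not use, with 4 on XHet, 6 on 3LHet, 3 on 2RHet and 1 on U, and a highest signal of 844. A search for dm6 optimal peaks of the same width and summit offset and a signal within 1% found a match for 4 of the 14, fewer than the 7 set before they were counted, and 1 of these 4 had 57 candidates. The search misses peaks on scaffolds placed in the other orientation, so a missing match does not show a missing peak. Pooled peaks outside the optimal set, also unused in the main comparisons, had 20.5% of summits within 500 bp of a coding start (4522 of 22064), against 11.4% for shuffled peaks. In those peaks the DRE share was 0.852% and the Sry-delta consensus share 2.02%.

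Exact DRE matches lay under 948 summits and Sry-delta consensus matches with at most 2 mismatches under 423, although matches of different length and stringency do not rank the sites, and 26.4% of summits held the consensus with at most 3 mismatches. Promoter location alone would give bound and unbound start sites equal shares, but the DRE lay within 250 bp of 21.0% of 6754 start sites with a summit and 1.72% of 12498 without, a ratio of 12.2. Very high transcription stays open: tRNA genes had an odds ratio of 0.0906, which met the bound written beforehand against it, but they are repeated copies read by another polymerase, and 24 of 24 housekeeping and 79 of 87 ribosomal protein genes were bound. Signal at active promoters that does not depend on the tagged protein also stays open, and cannot be told apart without a mock precipitation. Among promoter classes, the share of Motif 1 was 13.8% in the 1579 highest peaks and 11.8% in the 1579 lowest (odds ratio 1.2, exact adjusted p = 0.148), and that of Motif 6 was 9.63% and 12.4% (odds ratio 0.752, exact adjusted p = 0.0289), but Motif 7 stood at 48.9% and 12.6% (odds ratio 6.63), so promoter classes went different ways and neither side is settled.

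The Sry-delta consensus under summits was weighed against base composition and likeness to the DRE. Reordering its columns 200 times gave a ratio as high as the real 4.17 in 0 cases, with a median of 1.13 and a highest value of 2.33, which argues against base composition. Among 3955 peaks without TCGATA within 100 bp, the ratio was 3.06 (exact McNemar p = 3.44e-16), which argues against likeness to the DRE as the whole cause.

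Peaks around the Sry-delta gene had unusually high signals. The 5 optimal peaks within 10 kb had a median of 3721, reached around 0.284% of 10211 other coding genes with a peak in their window, and 2 of the 15 highest peaks lay there. Extra copies of the region from the tagging construct may raise them, and dividing the median by 2, as for a doubled copy number, left it reached around 2.78% of the other windows. The RpL32 signal divided by 2 would be 3514, at rank 51 in place of 1. The copy number and extent of the construct are not given in the sources used here, so extra copies and strong binding cannot be told apart. The peak at ZIPIC in the same window had a signal of 323 and rank 2464.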

How the results depend on the processing

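The alternative with 1 summit per region, pooled peaks as background and start sites in place of length were chosen after seeing the data, and the others before. Replicate overlap, the share near start sites, the Sry-delta consensus share, both splits by signal and the X density kept their direction and their side of the threshold under every alternative run for them. Overlap ranged from 70.4% for whole lists (shuffled mean 19.8%) to 92.4% for the stricter lists (shuffled mean 2.33%). The share near start sites ranged from 69.1% to 89.4% over the alternative windows, start sites and peak sets. Rank agreement was −0.00797 with the −log10 q column, which is saturated. The number of higher k-mers was 453 for 6-mers, of which 2080 exist, and 515 with the stricter peaks, which are fewer. Each replicate alone gave 629 to 885. Among lists not past the test, the odds ratio of dorsoventral and terminal genes turned to 1.24 with 1000 bp and 1.02 anywhere in the gene, and was 0.928 to 1.16 with each replicate alone. Zygotic genome activators turned to 0.558 with 1 start site per gene and 0 with the stricter peaks. Gut and fat body genes turned to 1.06 anywhere in the gene and were 0.636 to 1.2 with each replicate alone. The Initiator ratio was 0.979 with flanks 1000 bp away, and that of GAGA ran from 0.702 to 1.02 with each replicate alone. For these lists and motifs the cause was not tested. Lists past the test numbered 20 to 25, and the 20 of the main setting were all kept except with the stricter peaks, which shared 19. Of 86 named genes with a peak, 85 had one among the peaks used without replicate 3, and 86 among those used without replicate 4. The oc peak ranked 8291 in replicate 4, below the peaks used without replicate 3, so oc had no value there. The dm3 share near start sites and gene lists were not run, since no annotation of that build was used here. Unknown depth limits what the absence of a peak means.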

Other observations

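The tests in this part were chosen after the main results had been seen. Genes arranged head to head, with the most upstream start of an opposite-strand gene within 500 bp upstream of their own, were bound more often than others. Of 3481 such genes, 2604 (74.8%) had a summit within 500 bp of their most upstream start, against 2613 of 10464 other genes, an odds ratio of 8.92. A single summit between the starts of a pair counts for both genes, as at mRpL47 and CG8176.

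Peaks away from promoters differed in sequence from those near them. Of the 1535 peaks farther than 500 bp from a coding start, 4.69% held the CTCF site, named for an insulator protein, against 1.40% of the 4783 near peaks (odds ratio of near over far 0.289, exact adjusted p = 3.25e-12). The Sry-delta consensus was enriched over flanks by a ratio of 5.08 near starts and 2.03 far from them, and its share was 7.55% near and 4.04% far (exact adjusted p = 1.22e-06). The E-box was higher than its flanks near starts (ratio 1.52) but lower far from them (0.723). The ratio over flanks was 0.453 near starts and 1.21 far from them for Zelda sites, and 0.927 and 0.544 for GAGA repeats. The shares of these 2 motifs near and far did not differ past the test (exact adjusted p = 0.21 for Zelda and 0.334 for GAGA). Motif 7 rose with signal, from 12.6% of the 1579 lowest peaks to 48.9% of the 1579 highest, as did the DRE, from 4.31% to 31.3%, whereas Motif 6 fell from 12.4% to 9.63% and GAGA repeats from 4.56% to 2.03% (exact adjusted p = 0.0289 and 0.000252). The consensus and the DRE occurred together in 88 peaks, and the consensus was in 9.28% of peaks with the DRE and 6.24% of those without (odds ratio 1.54, exact p = 0.000891). The consensus also rose with signal, from 2.66% of the 1579 lowest peaks to 17.4% of the 1579 highest, and peaks of like signal were not compared. The odds ratio therefore does not show that the sites go together beyond their shared rise with signal. An exact match to the consensus lay under 3 summits, nearest to mago (rank 387), Src64B (rank 2267) and wech (rank 5580), of which Src64B and wech were singled out after their values had been seen.

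Secondary summits were not placed evenly. Of 835 paired with the highest summit of their region, 782 lay to its right in genome coordinates and 656 of them at an offset of at least 200 bp and under 300 bp. Among the 837 secondary summits, the DRE was in 13.4% of 69 bp windows centred 240 bp to the left and in 1.31% of those to the right, with 4.18% at the summit. For the highest summit of each region the shares were 0.438%, 0.474% and 9.29%. Whether the peak caller, which is not given in the sources used here, set this spacing was not tested, and the strand of the nearest gene was not compared.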
